A study of Mus musculus with 21 samples.

How the data were processed

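RNA of 15 aP2-Cre tumors, 3 Myogenin-Cre tumors and 3 normal muscle samples was measured on mouse bead arrays. RNA was extracted with Trizol, cleaned with RNeasy columns, treated with DNase and labelled with biotin, per the labels' protocols. The deposited table of values without normalization holds 1 linear intensity and 1 detection p-value per probe and array. The intensity had not been background-subtracted, since the lowest signal per array lay between 95.3 and 122, and the detection p-values moved in steps of 1 in 936. A second table deposited by the authors holds linear intensity values that were quantile normalized, separately in 5 sets of arrays, as the shared value distributions within each set show. BeadStudio is named in the submitters' processing notes, with no version; other steps are not given in the sources used here. Each column was matched to a sample by its label, except that 1 column of Myogenin-Cre tumor 42, whose letters are transposed, was matched by its number, and the rank correlation of a sample's 2 columns was at least 0.9999. The muscle arrays and aP2-Cre tumors 128, 135 and 140 form 1 set, the Myogenin-Cre tumors share 1 with aP2-Cre tumors 89, 90 and 95, and the other 3 sets hold aP2-Cre tumors only.

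The non-normalized intensities were background-corrected with normexp, using negative control parameters inferred from the detection p-values, an offset of 16 and quantile normalization (neqc in limma 3.58.1, R 4.3.3). Probes were kept if the detection p was under 0.01 on at least 3 arrays, which left 19655 of 45281. Of all probes, 34885 carry 1 gene symbol in the platform table, 18 carry several and 10378 none; probes without 1 symbol were not used. Of the probes with 1 symbol, 34807 matched a gene of the RefSeq table of assembly GRCm38.p6, used for names only, and 0 symbols changed. For each gene the probe with the highest mean over the 21 arrays was taken, giving 11034 genes. Between 32.0% and 39.8% of probes were detected per array.

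Differences were tested with limma (lmFit, contrasts.fit, eBayes with trend, two-sided) in 1 model over the 3 groups, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. A gene with a detection p of 0.01 or more on every array of a group has only a bound there: the bright group's mean was set against the mean over the dim group's arrays of the gene's own level or the array's lowest detected level, whichever was higher. For 23 gene lists fixed before the data were examined (Hedgehog response, myogenic regulators, developmental muscle, mature muscle, satellite cell, adipocyte, brown adipocyte, mesenchymal progenitor, cell cycle, p53 and inhibitors, IGF, Notch, extracellular matrix, oxidative phosphorylation, glycolysis, endothelial, macrophage, lymphocyte, erythroid, Schwann and nerve, epidermis, salivary gland and stress), camera was run with a preset correlation of 0.01 and with an estimated correlation, adjusted over 69 pairs of list and comparison. With the preset correlation 29 passed and with the estimated one 0; 10 had an unadjusted p under 0.05 with the estimated one. A listed name was looked up among synonyms only where it is no current symbol itself. Relations of list scores were tested with 100000 permutations.

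Named genes were 20 anchor genes in every comparison, per comparison the 6 largest rises and 6 largest falls among called genes whose group arrays did not overlap, and up to 4 members of each list in each direction with the smallest adjusted p. Of the anchor genes, 1 is not reported here. The fit was tested on simulated data with the real means and spreads. Of 100 genes changed 2-fold over 11034, it recovered 78% in the comparison of aP2-Cre tumors with muscle, 69% in that of Myogenin-Cre tumors with muscle and 77% between the tumors, and of 100 changed 4-fold 98%, 86% and 99%. Of all calls there, 8.33%, 5.49% and 5.38% were unchanged genes. Alternatives covered the background correction, the normalization, the authors' values, the probe filter, all probes, array weights, the naming series, each array of a group of 3 left out, and the 3 aP2-Cre tumors of the muscle arrays' naming series alone. Added after the data were seen were the set of arrays and Y-linked gene detection as covariates, the set shared by both kinds of tumor, and, for gene lists, every fit within a set or without 1 array. The array chip is not given in the column names, so it was not used. The genome build is not given in the sources used here, and no coordinates are printed.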

Results

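Gene expression was measured on bead arrays in 21 RNA samples of mice of mixed C57Bl/6 and 129X1/SvJ background. All animals carried SmoM2, an activated form of Smoothened, the receptor-like protein that switches on Hedgehog signalling. In 15 tumors SmoM2 had been switched on by Cre recombinase driven by the promoter of aP2 (Fabp4), a lipid-binding protein of adipocytes. In 3 tumors Cre was driven by the promoter of Myogenin, a transcription factor of differentiating muscle cells. The comparison tissue was 3 samples of sternocleidomastoid muscle, a neck muscle, from mice whose label gives the SmoM2 allele and names no Cre. The labels number a mouse for each tumor, and number the muscle samples 1 to 3 without saying whether they came from separate animals. The p-values rest on 1 spread pooled over the 3 groups, to which the 15 aP2-Cre tumors add most. Those against muscle may therefore leave out the spread between animals in muscle.

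On each array, 32.0% to 39.8% of 45281 probes had a detection p under 0.01. The share was 37.6% ± 1.2 (SD, n = 15) in aP2-Cre tumors, 36.1% ± 1.4 (SD, n = 3) in Myogenin-Cre tumors and 33.2% ± 1.2 (SD, n = 3) in muscle. Over 11034 genes, arrays of muscle correlated with each other at a median r of 0.984, aP2-Cre tumors at 0.96 and Myogenin-Cre tumors at 0.958, all across genes, which are not independent replicates. Between aP2-Cre tumors and muscle the median r was 0.844. The number of arrays, 3 in each of 2 groups, limits the precision of every value below. Levels are normalized log2 intensities, given as mean ± SD.

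The first comparison asked how aP2-Cre tumors differ from normal muscle. Targets of Hedgehog signalling were higher in the tumors. Ptch1, the Hedgehog receptor and a direct target of the pathway, had 6.28 ± 0.21 in muscle (n = 3) and 9.20 ± 0.37 in tumors (n = 15), a 7.56-fold rise (adjusted p = 2.46e-09). Hhip, a Hedgehog-binding protein that pathway activity induces, was not above background on any muscle array and was at least 4.66-fold higher in tumors (adjusted p = 4.49e-08). Smo, which is not counted here as a target, rose 2.42-fold (adjusted p = 7.9e-07). The tumors also carry switched-on SmoM2, and whether the Smo probe reads its transcript was not tested. Of the Hedgehog response list, 11 of 14 measured members rose and 0 fell, or 11 and 0 adjusted over the list alone, including Gli2, a transcription factor of the pathway, with a log2 change of 1.96, Ccnd1 with 2.58 and Foxf1, not above background in muscle and at least 3.45-fold higher (median log2 change 1.67, or 1.59 with undetected members at their bound, camera adjusted p = 0.0013, adjusted p = 0.26 with an estimated correlation). The single probe of Gli1 did not reach detection on any of the 21 arrays.

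Myog and Myod1, and the developmental muscle list, were higher in the tumors. Myog rose 28.0-fold, from 6.42 ± 0.20 to 11.23 ± 0.39 (adjusted p = 1.79e-12), and Myod1, the other transcription factor of this family that was measured above background, rose 7.99-fold (adjusted p = 9.2e-09). Of the myogenic regulator list, 7 of 14 measured members rose and 6 fell, or 7 and 6 adjusted over the list alone, with Meox1 at a log2 change of 2.99, and Lbx1 at -1.06 (median log2 change -0.03, camera adjusted p = 0.719, adjusted p = 0.774 with an estimated correlation). The list did not pass, and its median was below 0 while its mean and camera's direction were upward. Des, the muscle intermediate filament, rose only 1.27-fold (adjusted p = 0.00754). Of the developmental muscle list, 16 of 18 measured members rose and 1 fell, or 16 and 1 adjusted over the list alone (median log2 change 3.15, or 2.88 with undetected members at their bound, camera adjusted p = 8.22e-10, adjusted p = 0.106 with an estimated correlation). Myh8, the perinatal myosin heavy chain, rose from 8.19 ± 0.19 to 14.92 ± 0.30 (adjusted p = 6.47e-18). Chrng, the fetal acetylcholine receptor subunit, was not above background in muscle and was at least 155-fold higher. Myl4, the embryonic myosin light chain, changed by a log2 of 5.69, and Ankrd1, a muscle stress protein, by 6.86. Igf2, a growth factor, rose from 12.10 ± 0.02 to 15.05 ± 0.06 (adjusted p = 2.4e-19). In mean brightness over these tumors Igf2 ranked 5 and Myh8 12 of 11034 genes, and Myh8 had the highest value of the array on 3 of 15 arrays, so no fold is given for either. The single probes of Myf5 and Pax7 did not reach detection on any array, and Myh3 was not analysed here.

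Genes of adult muscle moved the other way. Of the mature muscle list, 2 of 28 measured members rose and 21 fell, or 2 and 21 adjusted over the list alone (median log2 change -1.40, camera adjusted p = 0.000548, adjusted p = 0.522 with an estimated correlation). Ckm, the muscle creatine kinase, fell from 15.10 ± 0.05, rank 5 of 11034 in brightness in muscle, so that no fold is given, to 11.91 ± 1.47 (adjusted p = 0.000984), with tumor 115 at 8.02 and the others at 10.38 or more. Casq1, the calcium store of the muscle fiber, and Pygm, the muscle glycogen phosphorylase, had log2 changes of -2.33 and -3.11. The members that rose were Tnnt1, the slow-fiber troponin T (log2 change 3.87), and Myh7, the slow myosin heavy chain (at least 3.91-fold). Acta1, the skeletal actin, ranked 7 of 11034 genes in brightness and did not pass the test (log2 change 0.06, adjusted p = 0.45), whereas with median centering of the arrays it was called lower (log2 change -0.32, adjusted p = 0.00735). Of the oxidative phosphorylation list, 0 of 25 measured members rose and 23 fell, or 0 and 23 adjusted over the list alone (median log2 change -1.16, camera adjusted p = 3.42e-08, adjusted p = 0.362 with an estimated correlation). Log2 changes included Cycs, cytochrome c, at -1.84 and Sdhb at -2.27. Of the glycolysis list, 2 of 15 measured members rose and 11 fell, or 2 and 11 adjusted over the list alone (median log2 change -0.70, camera adjusted p = 0.0269, adjusted p = 0.362 with an estimated correlation). Tpi1 had a log2 change of -1.54, and Hk1, not above background in muscle, was at least 2.9-fold higher.

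Fat genes were lower in the tumors than in muscle. The muscle pieces held RNA of genes of fat cells, so a fall here need not be a loss of expression in tumor cells. Pparg, the master regulator of fat cells, fell 8.36-fold from 9.84 ± 0.10 to 6.78 ± 0.41 (adjusted p = 2.99e-10), and Adipoq, a hormone of fat cells, fell 9.76-fold (adjusted p = 1.84e-05). Of the adipocyte list, 0 of 19 measured members rose and 18 fell, or 0 and 18 adjusted over the list alone (median log2 change -2.24, or -2.21 with undetected members at their bound, camera adjusted p = 1.9e-07, adjusted p = 0.296 with an estimated correlation), and Plin1, the coat protein of lipid droplets, fell to 4.79 ± 0.28, with detection on 2 of 15 arrays, from 7.41 ± 0.11. Ucp1, the uncoupling protein of brown fat, had 11.45 ± 0.62 in muscle and 4.67 ± 0.70 in tumors, where it reached detection on 2 of 15 arrays, so no fold is given (adjusted p = 9.64e-12). Of the brown adipocyte list, 2 of 13 measured members rose and 9 fell, or 2 and 9 adjusted over the list alone (median log2 change -1.77, or -1.31 with undetected members at their bound, camera adjusted p = 0.0117, adjusted p = 0.336 with an estimated correlation). The probe of Fabp4, whose promoter drove Cre in these mice, did not reach detection on any array.

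Proliferation, matrix and macrophage genes were higher. Of the cell cycle list, 19 of 27 measured members rose and 1 fell, or 20 and 1 adjusted over the list alone (median log2 change 1.23, or 0.70 with undetected members at their bound, camera adjusted p = 0.00849, adjusted p = 0.667 with an estimated correlation). Log2 changes included Mcm6, a helicase subunit of DNA replication, at 1.92, Bub1b at 2.18 and Aurka, the single member that fell, at -1.12. Bub1b reached detection with any probe on 1 of 3 muscle arrays, so the size of its change is uncertain. Mki67 was not analysed here. Of the extracellular matrix list, 23 of 25 measured members rose and 0 fell, or 24 and 0 adjusted over the list alone (median log2 change 1.69, camera adjusted p = 5.04e-07, adjusted p = 0.362 with an estimated correlation). Log2 changes included the proteoglycan Bgn at 3.07 and Tnc, tenascin C, at 4.65. Of the macrophage list, 12 of 13 measured members rose and 0 fell, or 12 and 0 adjusted over the list alone (median log2 change 1.77, camera adjusted p = 0.000426, adjusted p = 0.362 with an estimated correlation). Log2 changes included C1qb, a complement component made by macrophages, at 2.68 and Aif1 at 2.91. Of the IGF list, 9 of 14 measured members rose and 3 fell, or 9 and 3 adjusted over the list alone (median log2 change 0.94, camera adjusted p = 0.0137, adjusted p = 0.193 with an estimated correlation). Log2 changes included Igfbp3 at 3.42. Of the satellite cell list, 8 of 11 measured members rose and 1 fell, or 8 and 3 adjusted over the list alone (median log2 change 1.28, camera adjusted p = 0.0422, adjusted p = 0.362 with an estimated correlation). Log2 changes included Megf10 at 4.43. Of the Notch list, 6 of 11 measured members rose and 0 fell, or 6 and 0 adjusted over the list alone (median log2 change 0.79, camera adjusted p = 0.0462, adjusted p = 0.362 with an estimated correlation). Log2 changes included Hey1, a Notch target, at 2.48.

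Among cell cycle inhibitors and p53 genes, 8 of 14 measured members rose and 2 fell, or 8 and 2 adjusted over the list alone (median log2 change 0.78, or 0.70 with undetected members at their bound, camera adjusted p = 0.0506, adjusted p = 0.336 with an estimated correlation), so the list did not pass, although Cdkn1a, the inhibitor p21, had a log2 change of 3.31. Cdkn2a, which encodes the inhibitors p16 and p19Arf, reached detection with the probe used on 7 of 15 tumor arrays, with any of its probes on 8, and on 0 muscle arrays, with a level of 5.63 ± 0.98 in tumors, (adjusted p = 0.0389). Its mean in tumors lay below the detection floor of the muscle arrays, so no fold is given. The highest levels, 6.06 to 7.42, were those of tumors 64, 65, 68, 115, 165 and 174, all in array sets without muscle. Tumors 128, 135 and 140, in the set of the muscle arrays, had 4.82 to 5.37, against 4.33 to 4.44 in muscle. Other lists did not pass: mesenchymal progenitor (adjusted p = 0.563), endothelial (0.83), lymphocyte (0.614), erythroid (0.372), Schwann and nerve (0.177), epidermis (0.416), salivary gland (0.775) and stress (0.567). In the salivary gland list the median was above 0, and the mean and camera's direction were downward. By size of change, the 6 largest fitted rises with every tumor array above every muscle array were those of Chrng, Sct (secretin, at least 78.7-fold), Ankrd1, Myh8, Dlk1 (65.7-fold), an inhibitor of fat cell formation, and Sox11 (at least 32.8-fold). Chrng, Sct and Sox11 were not detected in muscle, so their ranks rest on fitted values, and the bound of Sox11 lies below the 51.6-fold rise of Myl4. Myh8 ranked 12 in brightness in these tumors, so its place rests on a value near the upper end of the scale. The 6 largest fitted falls were those of Ucp1, the fast myosin Myh4 (87.1-fold), Lrrc38, Gpd1 (27.7-fold), Phkg1 (23.7-fold) and Plcd4. Lrrc38 and Plcd4 reached detection on only 3 and 6 of 15 tumor arrays, so no fold is given for them.

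In all, limma called 3757 genes higher and 3285 lower in aP2-Cre tumors, of 11034, at an adjusted p under 0.05, and 1737 and 1435 of these changed at least 2-fold. With arrays centered on their median instead of quantile normalized, 5066 were higher and 1722 lower, and the median of all genes moved from 0.09 to 0.44 (log2). The authors had normalized the arrays in 5 sets, and within the set of 3 tumors and 3 muscle arrays the counts were 3427 and 3109, with list medians of 1.62 for Hedgehog, 3.37 for developmental muscle, -1.21 for mature muscle, -2.14 for adipocyte and 0.63 for cell cycle genes. In that set, at the preset correlation, the satellite cell list did not pass (adjusted p = 0.0548), whereas the p53 and inhibitor list (adjusted p = 0.0416) and the Schwann and nerve list (adjusted p = 0.04, median -0.99) did. With the set as a covariate the cell cycle and Notch lists did not pass (adjusted p = 0.102 and 0.0556) and the p53 and inhibitor list did (adjusted p = 0.0456), and with median centering the IGF list did not pass (adjusted p = 0.0561).

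**Figure D1:**
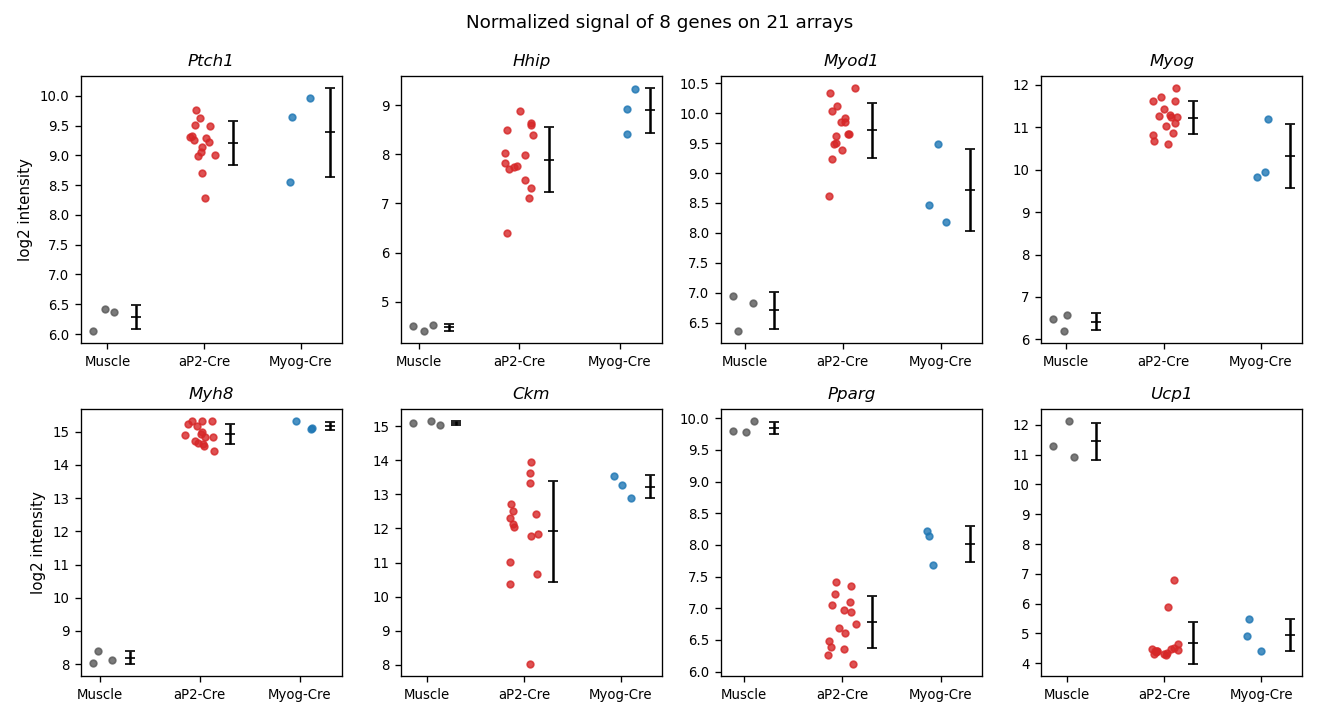
Normalized log2 intensity (vertical axis) of 8 genes in 3 muscle, 15 aP2-Cre and 3 Myogenin-Cre arrays; each point is an array, and the bar beside each group is its mean and SD. For Myh8 all tumor arrays lie above all muscle arrays, with means of 14.92 and 15.17 in the tumors against 8.19, and for Ucp1 all tumor arrays lie below.

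The second comparison set the 3 Myogenin-Cre tumors against the same muscle. The Hedgehog targets were again high. Ptch1 rose 8.61-fold to 9.39 ± 0.74 (SD, n = 3, adjusted p = 1.25e-07), Hhip was at least 9.33-fold higher, and Gli2 had a log2 change of 2.63. Smo, whose probe may also read SmoM2, rose 3.03-fold. Of the Hedgehog response list, 10 of 14 measured members rose and 0 fell, or 10 and 0 adjusted over the list alone (median log2 change 1.28, or 1.10 with undetected members at their bound, camera adjusted p = 0.000296, adjusted p = 0.193 with an estimated correlation). Myog rose 14.9-fold to 10.32 ± 0.75 (adjusted p = 8.57e-09) and Myod1 3.99-fold to 8.71 ± 0.68 (adjusted p = 0.000111). Of the myogenic regulators, 4 of 14 measured members rose and 5 fell, or 4 and 5 adjusted over the list alone (median log2 change 0.38, camera adjusted p = 0.719, adjusted p = 0.774 with an estimated correlation). Des did not pass the test (log2 change 0.30, adjusted p = 0.0695). Of the developmental muscle list, 16 of 18 measured members rose and 0 fell, or 16 and 0 adjusted over the list alone (median log2 change 2.79, camera adjusted p = 1.11e-11, adjusted p = 0.0751 with an estimated correlation), with Chrng at least 79.6-fold higher. Myh8 rose to 15.17 ± 0.13 and Igf2 to 14.97 ± 0.09 (adjusted p = 6.38e-16 and 9.07e-17), and no fold is given, as they ranked 4 and 11 of 11034 genes in brightness there.

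Mature muscle genes were lower in part. In that list, 1 of 28 measured members rose and 12 fell, or 1 and 12 adjusted over the list alone (median log2 change -0.92, camera adjusted p = 0.0117, adjusted p = 0.633 with an estimated correlation). Log2 changes included Casq1 at -2.38 and Pygm at -2.30. Ckm had a level of 13.23 ± 0.33 against 15.10 ± 0.05 in muscle, with every tumor array below every muscle array, yet was not called (adjusted p = 0.123). The spread in this test was pooled over the 3 groups, and the SD of Ckm in aP2-Cre tumors was 1.47. Acta1 had a log2 change of 0.04 (adjusted p = 0.736), or with median centering -0.49 (adjusted p = 0.00357, called lower). Of the oxidative phosphorylation list, 0 of 25 measured members rose and 19 fell, or 0 and 19 adjusted over the list alone (median log2 change -0.77, camera adjusted p = 0.000296, adjusted p = 0.568 with an estimated correlation), and of the glycolysis list, 2 of 15 measured members rose and 10 fell, or 2 and 11 adjusted over the list alone (median log2 change -0.77, camera adjusted p = 0.0232, adjusted p = 0.362 with an estimated correlation). Fat genes were lower, with Pparg 3.56-fold and Adipoq 6.77-fold below muscle. Of the adipocyte list, 0 of 19 measured members rose and 14 fell, or 0 and 14 adjusted over the list alone (median log2 change -1.83, or -1.80 with undetected members at their bound, camera adjusted p = 1.87e-06, adjusted p = 0.336 with an estimated correlation), and of the brown adipocyte list, 0 of 13 measured members rose and 4 fell, or 0 and 4 adjusted over the list alone (median log2 change -0.76, camera adjusted p = 0.0512, adjusted p = 0.362 with an estimated correlation), which did not pass as a list, with Ucp1 at 4.94 ± 0.54 and detected on 1 of 3 tumor arrays. Extracellular matrix genes were higher, as 16 of 25 measured members rose and 0 fell, or 16 and 0 adjusted over the list alone (median log2 change 1.24, camera adjusted p = 8.86e-06, adjusted p = 0.362 with an estimated correlation). Of the IGF list, 8 of 14 measured members rose and 0 fell, or 8 and 0 adjusted over the list alone (median log2 change 1.23, camera adjusted p = 0.000268, adjusted p = 0.0751 with an estimated correlation). Log2 changes included Igfbp3 at 3.09. Of the satellite cell list, 7 of 11 measured members rose and 2 fell, or 7 and 2 adjusted over the list alone (median log2 change 1.27, camera adjusted p = 0.0462, adjusted p = 0.362 with an estimated correlation). The cell cycle list did not pass (adjusted p = 0.0541), and 9 of 27 measured members rose and 1 fell, or 9 and 1 adjusted over the list alone.

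Cdkn2a did not reach detection in muscle or in Myogenin-Cre tumors. The remaining lists did not pass: macrophage (adjusted p = 0.284), Notch (0.284), p53 and inhibitors (0.0929), mesenchymal progenitor (0.372), endothelial (0.508), lymphocyte (0.897), erythroid (0.772), Schwann and nerve (0.642), epidermis (0.221), salivary gland (0.903) and stress (0.784). Camera's direction was downward where the salivary gland list's median and mean, and the lymphocyte list's mean, were above 0. By size of change, the 6 largest fitted rises were those of Chrng, Myh8, Sct (at least 56.2-fold), Ankrd1 (83.3-fold), Sln, the inhibitor of the muscle calcium pump (76.3-fold), and Dlk1 (73.5-fold). Chrng and Sct were not detected in muscle, so their ranks rest on fitted values, and their bounds do not set their order. Sln and Dlk1 ranked 27 and 37 in brightness in these tumors. Myh8 ranked 4, so its place in this order rests on a value near the upper end of the scale. The 6 largest fitted falls were those of Ucp1, Myh4 (42.4-fold), Lrrc38 and Plcd4, detected on 2 and 1 of 3 tumor arrays, Smr3a, a salivary protein (at least 13.4-fold), and Chia1, a chitinase (at least 10.6-fold). Smr3a and Chia1 reached detection on 2 of 3 muscle arrays each, with levels of 9.13 ± 4.79 and 8.79 ± 4.64, and the salivary gland scores of muscle 1, 2 and 3 were -1.72, 2.69 and -0.93. Limma called 2778 genes higher and 2635 lower, 1389 and 1176 of them by at least 2-fold. Median centering gave 2945 and 1398, with the median of all genes at 0.25 against 0.06. No set of arrays normalized together held both groups, and with the set as a covariate, linked through aP2-Cre tumors, 2029 genes were higher and 2004 lower. The mature muscle and satellite cell lists did not pass with that covariate at the preset correlation (adjusted p = 0.0699 and 0.102). With the authors' values the satellite cell list did not pass and the cell cycle list did (adjusted p = 0.0559 and 0.0116), and with median centering the brown adipocyte list passed (adjusted p = 0.0065).

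**Figure D2:**
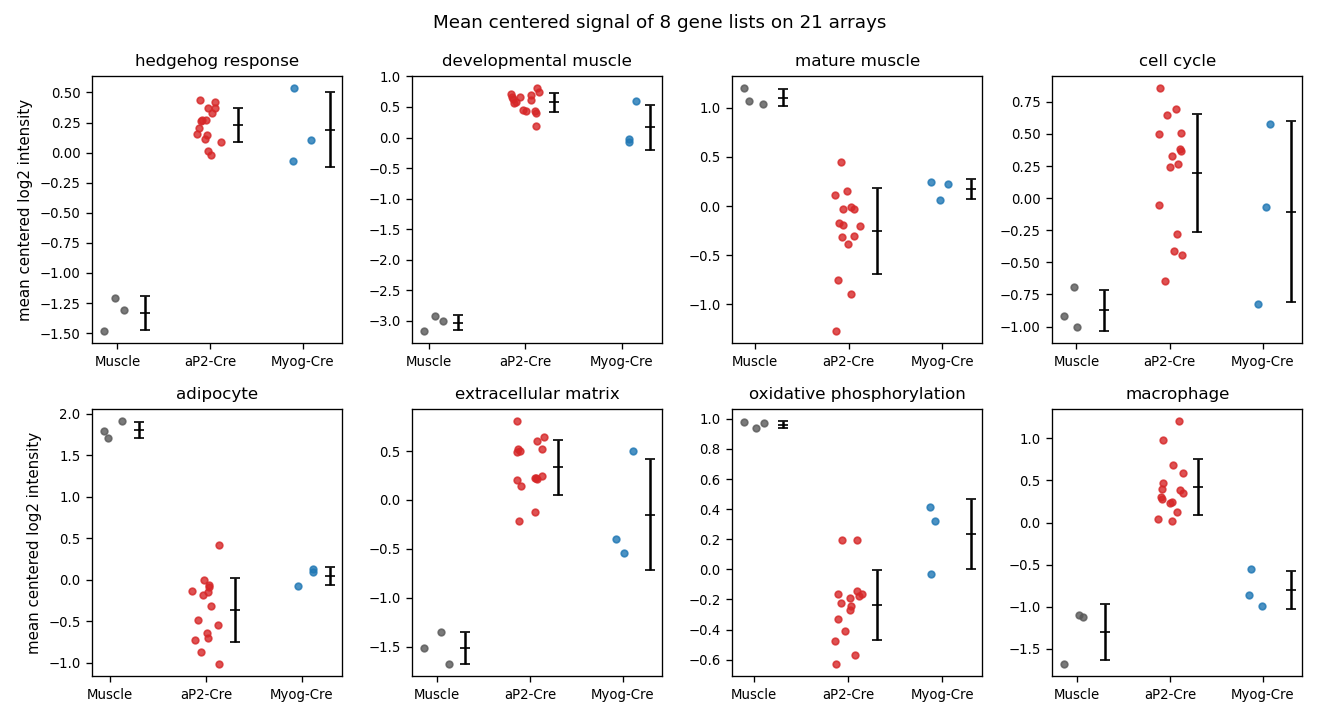
Mean over each list's measured members of the log2 intensity centered on the gene's mean over 21 arrays (vertical axis), for 8 lists; each point is an array, and the bar beside each group is its mean and SD. Macrophage scores of the 15 aP2-Cre tumors lie above those of the 3 Myogenin-Cre tumors, and the adipocyte scores of muscle lie above those of every tumor.

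The 2 tumor models changed largely in parallel. Limma called 2468 genes higher in both and 2382 lower in both, against 946 and 784 for independent lists of these sizes, while 12 genes were called in opposite directions. Fold changes correlated across genes at r = 0.88. Both comparisons share the 3 muscle arrays. In 100 simulations of 3 unchanged groups, with genes drawn independently, r was 0.65 from the shared arrays alone. Calls in both were 0 on average there, but groups without change give almost no calls, so this 0 cannot gauge the overlap. The covariance was 1.05 against 0.0639 simulated. Muscle has too few arrays for a split into parts with at least 2 arrays each, so part of the excess may come from the shared arrays.

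The third comparison tested whether tumors started by the 2 Cre drivers differ. The macrophage list was higher in aP2-Cre tumors. Among the 6 largest fitted rises, H2-Eb1, H2-Aa and H2-Ab1, chains of the MHC class II complex, had log2 changes of 4.05, 3.90 and 3.70, and Cd74, the invariant chain, was 15.9-fold higher (adjusted p = 1.34e-05), from 8.97 ± 1.00 (SD, n = 3) to 12.96 ± 0.80 (SD, n = 15). In muscle H2-Eb1, H2-Aa, H2-Ab1 and Cd74 had means of 9.14, 7.90, 9.87 and 10.24, between those of the 2 kinds of tumor. Of the macrophage list, 9 of 13 measured members were higher and 1 lower, or 11 and 1 adjusted over the list alone (median log2 change 1.60, camera adjusted p = 4.81e-09, adjusted p = 0.193 with an estimated correlation). Log2 changes included Aif1 at 2.55, Fcgr3 at 1.86 and C1qc at 1.61, while Cd163 was lower at -1.71. Mmp10, a matrix protease, was 22.1-fold higher and Acan, the cartilage proteoglycan, at least 6.76-fold higher. Mmp10 and H2-Aa each reached detection on 2 of 3 Myogenin-Cre arrays, so the size of their changes is uncertain. Of the extracellular matrix list, 7 of 25 measured members were higher and 2 lower, or 11 and 2 adjusted over the list alone (median log2 change 0.45, camera adjusted p = 0.00288, adjusted p = 0.568 with an estimated correlation). Log2 changes included Lum at 1.89 and Col4a1 at -0.52. Of the developmental muscle list, 6 of 18 measured members were higher and 0 lower, or 9 and 0 adjusted over the list alone (median log2 change 0.42, camera adjusted p = 0.0066, adjusted p = 0.4 with an estimated correlation). Log2 changes included Mymk, a protein of muscle cell fusion, at 1.15. Of the Notch list, 4 of 11 measured members were higher and 0 lower, or 4 and 0 adjusted over the list alone (median log2 change 0.23, camera adjusted p = 0.0236, adjusted p = 0.362 with an estimated correlation). Log2 changes included Hes1 at 0.73. These 3 list differences rest on Myogenin-Cre tumors 41 and 43. Tumor 42 scored 0.50 for extracellular matrix, 0.59 for developmental muscle and 0.19 for Notch, within the aP2-Cre ranges of -0.22 to 0.81, 0.20 to 0.81 and -0.06 to 0.40.

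The oxidative phosphorylation list and part of the adipocyte list were lower in aP2-Cre tumors. Of the oxidative phosphorylation list, 0 of 25 measured members were higher and 13 lower, or 0 and 18 adjusted over the list alone (median log2 change -0.52, camera adjusted p = 1.15e-08, adjusted p = 0.362 with an estimated correlation). Log2 changes included Atp5c1 at -0.69 and Cox5a at -0.57. Of the adipocyte list, 0 of 19 measured members were higher and 5 lower, or 0 and 5 adjusted over the list alone (median log2 change -0.26, camera adjusted p = 0.0142, adjusted p = 0.568 with an estimated correlation), with Pparg 2.35-fold lower (adjusted p = 0.00121) and Lpl at -1.28. Of the mature muscle list, 1 of 28 measured members were higher and 2 lower, or 1 and 2 adjusted over the list alone (median log2 change -0.35, camera adjusted p = 0.0117, adjusted p = 0.633 with an estimated correlation). For oxidative phosphorylation, Myogenin-Cre tumors 41 and 43 scored 0.41 and 0.32, above the aP2-Cre range of -0.63 to 0.20, and tumor 42 scored -0.03, within it. For adipocyte and mature muscle genes all 3 lay within the aP2-Cre ranges, with 0.13, -0.08 and 0.09 in -1.02 to 0.41, and 0.24, 0.06 and 0.22 in -1.27 to 0.45. The 6 largest fitted falls were those of Stfa2 (at least 7.54-fold) and Stfa1 (detected on 3 of 15 aP2-Cre arrays), stefins of the cystatin family, Fbp2 (11.2-fold), the muscle fructose bisphosphatase, Acot1 (9.61-fold), Kcne1l (9.23-fold) and Plin5 (7.53-fold), a lipid droplet protein. Stfa2 had 8.18 ± 2.02 and Stfa1 8.12 ± 1.85 in the 3 Myogenin-Cre tumors, so the size of these 2 falls is uncertain. Myod1 was 2.0-fold higher (adjusted p = 0.0198) and Myog 1.88-fold higher (adjusted p = 0.0203) in aP2-Cre tumors. Both differences rest on Myogenin-Cre tumors 41 and 43, with 8.46 and 8.18 for Myod1 and 9.94 and 9.83 for Myog. Tumor 42, with 9.48 and 11.19, lay within the aP2-Cre ranges of 8.62 to 10.41 and 10.61 to 11.92. Of the Hedgehog response list, 3 of 14 measured members were higher and 2 lower, or 3 and 3 adjusted over the list alone, and the list did not pass (adjusted p = 0.897). Ccnd1, Cdon and Foxf1 were higher, at 1.00, 1.06 and 0.86, and Gli2 and Evc lower, at -0.67 and -0.53 (log2). Hhip had 7.89 ± 0.66 in aP2-Cre and 8.89 ± 0.45 in Myogenin-Cre tumors (adjusted p = 0.0591), while Ptch1 had a log2 change of -0.19 (adjusted p = 0.648) and Smo of -0.32 (adjusted p = 0.186). None of Des (0.04), Myh8 (-0.25), Acta1 (0.02), Ckm (-1.32), Adipoq (-0.53) or Igf2 (0.08) passed, these being log2 changes, and Myh8, Acta1 and Igf2 were near the upper end of the scale in both kinds of tumor. Cdkn2a, undetected in Myogenin-Cre tumors, did not pass either (at least 1.18-fold, adjusted p = 0.107).

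The other lists did not pass in this comparison: myogenic regulators (adjusted p = 0.284), satellite cell (0.254), brown adipocyte (0.0837), mesenchymal progenitor (0.966), cell cycle (0.0651), p53 and inhibitors (0.257), IGF (0.416), glycolysis (0.8), endothelial (0.419), lymphocyte (0.182), erythroid (0.187), Schwann and nerve (0.0603), epidermis (0.416), salivary gland (0.676) and stress (0.369). Camera's direction was downward where the median of the Hedgehog and mesenchymal progenitor lists, and the mean of the Hedgehog list, were above 0. Limma called 891 genes higher and 847 lower in aP2-Cre tumors, 296 and 249 by at least 2-fold. Median centering gave 1034 and 226, with the median of all genes at 0.17 against 0.01, and the authors' values gave 207 and 322. Without Myogenin-Cre tumor 43 the counts fell to 196 and 170, and without tumor 41 to 311 and 304. Within the set of 3 aP2-Cre and 3 Myogenin-Cre tumors normalized together, 33 genes were higher and 12 lower, and with the set as a covariate 201 and 208. List medians within that set were 1.30 for macrophage, -0.35 for oxidative phosphorylation, 0.53 for extracellular matrix, 0.37 for developmental muscle, -0.24 for adipocyte and -0.20 for mature muscle genes. Only 2 macrophage members and 1 adipocyte member were called within it, all of them higher, and 0 members of the other lists just named. The cell cycle list passed there at the preset correlation (median 0.52, adjusted p = 0.000928) and with the set as a covariate (adjusted p = 0.00167), while the mature muscle list did not pass with that covariate (adjusted p = 0.0699) or with the authors' values (adjusted p = 0.0684). Within the set 0 of 27 cell cycle members were called, and Myogenin-Cre tumors 41, 42 and 43 scored -0.07, 0.58 and -0.82. The aP2-Cre tumors of the set scored 0.26 to 0.64, so tumor 42 lay within their range. Without Myogenin-Cre tumor 43 the Notch list did not pass (adjusted p = 0.149). With median centering the brown adipocyte, erythroid and Schwann and nerve lists passed as lower (adjusted p = 0.00603, 0.0237 and 0.0156).

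Across the 15 aP2-Cre tumors, 3 relations between list scores were computed. Cell cycle and mature muscle scores had Pearson's r = -0.53 (permutation p = 0.0422, Benjamini-Hochberg adjusted p = 0.126) and Spearman's rho = -0.76 (permutation p = 0.00137, adjusted p = 0.00411). Which of the tests passed depended on the scaling: with genes divided by their SD, r was -0.68 (adjusted p = 0.016) and rho -0.83 (adjusted p = 0.00063), and with median centering rho was -0.43 (adjusted p = 0.165). Without the 2 tumors farthest from the median on cell cycle, r was -0.52 (permutation p = 0.0676). Among the 12 tumors of one naming series r was -0.46, and with scores centered within each set of 3 arrays it was -0.60; a set of 3 holds too few tumors for a value of its own. Hedgehog and cell cycle scores had r = 0.21 and rho = 0.23 (adjusted permutation p = 0.578 and 0.607; r without the 2 tumors farthest out 0.44). Adipocyte and myogenic regulator scores had r = 0.16 and rho = 0.0321 (adjusted permutation p = 0.578 and 0.913; r without the 2 tumors farthest out -0.0839). With median centering r for this pair was 0.63 (adjusted permutation p = 0.0363) and with the authors' values 0.61 (adjusted permutation p = 0.0497), both past the threshold. With the authors' values the cell cycle relation had rho = -0.16 (adjusted permutation p = 0.574).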

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

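The tests for fat tissue in the muscle pieces and for normal muscle in the Myogenin-Cre tumor pieces were chosen after the values they rest on had been seen. The change from muscle differed between the 2 tumor models, by the test of the difference itself, for 1738 genes, and 12 genes were called in opposite directions. Among anchor genes the difference passed for Myod1 (log2 1.00), Myog (log2 0.91) and Pparg (log2 -1.23), aP2-Cre minus Myogenin-Cre. Among lists it passed for developmental muscle (median log2 0.42), mature muscle (-0.35), adipocyte (-0.26), Notch (0.23), extracellular matrix (0.45), oxidative phosphorylation (-0.52) and macrophage genes (1.60), each with the preset correlation only. Myogenin-Cre tumor 42 lay within the aP2-Cre range for Myod1, Myog and each of these lists except macrophage, and tumors 41 and 43 did so for mature muscle and adipocyte genes. Among the probes without 1 gene name, which the comparisons did not use, 57 were detected on every tumor array and on no muscle array. Of 100 splits of the 18 tumors into 15 and 3, 1 gave as many called genes as the real 1738, the real one itself. The highest other gave 744, so random splits that ignore the array sets gave as many in a share under 0.05. All 3 Myogenin-Cre tumors lie in 1 set, and with the set as a covariate 201 genes were higher and 208 lower, or 33 and 12 within that set. For aP2-Cre tumors against muscle 1 of 100 splits, the real one, gave 7042 genes and the highest other 3879. That share is under 0.05 too. Muscle is another tissue and its arrays lie in 1 set, so these splits cannot speak to an effect of the sets. For Myogenin-Cre tumors against muscle the real split, 1 of 10, gave 5413 genes and the highest other 0, and 10 splits are too few for a share under 0.05.

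Macrophage genes were higher in aP2-Cre than in Myogenin-Cre tumors by a median log2 of 1.60. The values used here were normalized over all 21 arrays together, so the authors' separate normalization does not enter them. They argue against a difference that follows the array sets. Within the set that holds both kinds of tumor the median was 1.30, between 1.18 and 1.48 without each array. There 12 of 13 members were higher, although only 2 were called. A single Myogenin-Cre tumor is not the source either, as the median nearest to 0 without 1 of them was 1.48. A difference in the share of macrophages, in their state, or between the Cre drivers stays open and was not tested.

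Adipocyte genes were lower in tumors than in muscle. For aP2-Cre tumors, a difference between array sets does not account for it. The median log2 was -2.14 within the set of 3 tumors and 3 muscle arrays. Neither does quantile normalization, with -2.24 relative to all genes after median centering. No set held Myogenin-Cre tumors with muscle, so array sets were not tested that way for them. The adipocyte median relative to all genes was not computed for them. With median centering, however, their brown adipocyte list passed camera as lower (median log2 -0.82, adjusted p = 0.0065). Of 22 tested adipocyte and brown adipocyte genes, leaving out 10 that muscle fibers also express, 17 were lower in aP2-Cre and 14 in Myogenin-Cre tumors, 0 of the 32 are in another list, and the most abundant in muscle were Scd1, with 13.17 ± 0.71, and Cidea, with 12.45 ± 0.29. Adipoq had 11.92 ± 0.20 and Ucp1 11.45 ± 0.62 in muscle, so the muscle pieces held RNA of fat genes not counted among those of muscle fibers. These levels in muscle itself argue against a lower expression in the tumors as the only source of the difference. Fat tissue in the muscle pieces and a lower expression of fat genes in the tumors would both give such counts of lower genes. How much each adds cannot be told from them.

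Oxidative phosphorylation genes were lower in aP2-Cre than in Myogenin-Cre tumors by a median log2 of -0.52. Without 1 Myogenin-Cre tumor the median nearest to 0 was -0.37, and tumor 42 scored -0.03, within the aP2-Cre range of -0.63 to 0.20, so the difference rests on tumors 41 and 43. By the bound set beforehand, array sets cannot be told apart from the driver, as the median within the shared set was -0.35, from -0.50 to -0.23 without each array, the last of these nearer to 0 than 0.5 of the median over all arrays, although 25 of 25 members were lower there, 0 of them called. Normal muscle in the Myogenin-Cre tumor pieces could add to it, but the mature muscle list had a median of -0.35, less far below 0 than the list it would have to explain and not above 0, which leaves it open.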

How the results depend on the processing

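The set covariate, the set shared by both kinds of tumor and Y-linked gene detection were chosen after the data were seen, as were, for gene lists, the fits within a set and without 1 array; the 3 tumors with 3 muscle arrays were planned for gene counts. Of 3011 values of named genes under alternatives, 2773 kept their direction and side of the threshold, 205 lost the call, 11 gained it and 22 changed sign; the cause was not tested. Median centering left 1722 genes lower in aP2-Cre tumors than in muscle, 1398 in Myogenin-Cre tumors and 226 between tumors, with 5066, 2945 and 1034 higher. Counted as probes, 6170 and 6040, 4529 and 4859, and 1353 and 1430 were higher and lower, since more items are tested. Between tumors the authors' values gave 207 and 322, array weights 1661 and 1431, the set covariate 201 and 208 and the shared set alone 33 and 12, with fewer samples. Leaving out 1 array gave 196 to 1188 higher and 170 to 1005 lower between tumors, lowest without Myogenin-Cre tumor 43 and highest without tumor 42. No gene list passed with an estimated correlation (0 of 69). The overlap with at least a 2-fold change was 1104 higher and 972 lower, fewer by construction, and with median centering 1182 were lower in both. For list scores, cell cycle with mature muscle had rho -0.43 with median centering (adjusted p = 0.165) and -0.16 with the authors' values (adjusted p = 0.574), and r -0.68 with genes scaled by their SD (adjusted p = 0.016). Adipocyte with myogenic regulators had r 0.63 with median centering (adjusted p = 0.0363), 0.61 with the authors' values (adjusted p = 0.0497) and -0.0839 without 2 tumors. Signs turned for Acta1 against muscle in aP2-Cre tumors (-0.32 with median centering, adjusted p = 0.00735, -0.20 with the authors' values) and in Myogenin-Cre tumors (-0.49, adjusted p = 0.00357, -0.29, -0.00859 to 0.0698 without 1 array); Cdkn2a in Myogenin-Cre tumors (-0.0526 with median centering, -0.022 with array weights, -0.68 with the naming series, -0.12 with Y-linked detection, -0.0205 to 0.0667 without 1 array). Between tumors, signs turned for Des (-0.0136 with the authors' values, -0.0508 with the set as covariate and alone, -0.0678 to 0.12 without 1 array), Ptch1 (0.12 with array weights, -0.61 to 0.0992 without 1 array), Myh8 (0.0962 with the set as covariate and alone) and Acta1 (-0.0195 with the set as covariate and alone, -0.00100 to 0.039 without 1 array). The chip could not be used, as the columns do not name it. Tumors and muscle samples of the shared set with the same number in their column names deviated together with r of -0.16, -0.13 and 0.0676. These values gave no sign that the numbers pair them, but cannot show that they do not. A replicate block there gave 3251 and 2970 genes against 3427 and 3109. Signal over background limits Gli1, Myf5, Pax7 and Fabp4, which reached detection on no array. Each has 1 probe, so a gene that is not expressed and a probe that gives no signal cannot be told apart.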

Other observations

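Among the 12 genes called in opposite directions in the 2 models, the following were picked after their values were seen, because they are known to be induced by interferon, and they do not stand for such genes as a group. Isg15 had 6.91 ± 0.09 (SD, n = 3) in muscle, 7.80 ± 0.41 (SD, n = 15) in aP2-Cre and 6.10 ± 0.32 (SD, n = 3) in Myogenin-Cre tumors. Usp18, Oas1g, Dhx58 and Irf9 were likewise called higher than muscle in one model and lower in the other, with differences between models of 2.47, 2.58, 1.80 and 1.21 (log2), and of 2.36, 2.25, 1.92 and 1.22 within the set normalized together. Also among the 12, B2m, a chain of MHC class I, differed by 1.83 and the chemokine Cxcl14 by 3.15.

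Xist, the RNA of the inactive X chromosome, reached detection on 3 of 3 muscle, 9 of 15 aP2-Cre and 1 of 3 Myogenin-Cre arrays, and the Y-linked Eif2s3y on 0, 6 and 2. The mix of sexes differs between the groups.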
